A study of Mus musculus with 9 samples.

How the data were processed

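RNA from mouse embryonic fibroblasts of the C57BL/6 strain was sequenced in 9 libraries, 3 from cells given an empty lentiviral vector, 3 from cells overexpressing p21 and 3 from cells overexpressing p16. Per the labels' protocols, RNA was taken 10 days after overexpression with a column kit and made into libraries with a TruSeq version 2 kit, which does not mark the strand. Group and replicate number were taken from the sample titles. The record numbers of the p16 libraries do not run on from those of the control and p21 libraries. If the p16 libraries were also prepared or sequenced apart, that would be confounded with p16 in both its comparisons. The status label of the control libraries also reads senescent, although their titles name the empty vector as control. Nothing in the labels says whether the replicates came from separate embryos or cultures, so p-values measure only the spread between these libraries. Part of it is not technical, since replicate 3 of each group differs in sex-linked transcripts. For replicates 1 and 2 it may be.

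The deposited table holds whole-number read counts per gene symbol for 24062 genes, which the authors did not normalise. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.2.6, Subread and featureCounts 1.4.6 were used with the mouse build mm10. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes and of near-identical copies could therefore be split or lost, and histone, H2, Lce and Serpinb9 family members are uncertain for that reason. Counts for Cdkn2a do not separate the transcripts of p16 and of p19Arf. Counts for Cdkn1a and Cdkn2a do not separate vector-derived from endogenous transcripts, and whether the constructs hold mouse sequence is not stated in the labels. The table lists no mitochondrially encoded gene under the names searched, so that list was not tested. Gene positions are those of GENCODE M21 on GRCm38, the assembly also called mm10.

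Library totals ran from 56.9 M counts (M, 10 to the power 6) in p21 replicate 3 to 76.1 M in control replicate 1, and 5111 genes had no read in any library. Genes were kept by edgeR's filterByExpr with the groups given, which left 14572 genes holding at least 99.985% of the counts of each library. Every pair of libraries within a group differed beyond sampling noise, with a chi-square per degree of freedom from 10.37 to 101.2, so none was merged as a repeated reading of the same library. Any 2 preparations can differ so, and this does not show separate cultures.

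The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and a single fit of the 3 group means to the 9 libraries. Contrasts were p21 minus control, p16 minus control and p21 minus p16, each with Benjamini-Hochberg adjustment and a threshold of 0.05. The p21 minus p16 contrast is also the test of whether the effects of p21 and p16 differ. Standard errors of log2 fold changes are the fold change divided by the root of F. Levels are CPM, counts scaled to a library total of 1 M after TMM, given as mean ± SD over 3 libraries.

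Before the data were examined, 34 gene lists were fixed, of which 8 hold markers of other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The list tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. With an estimated correlation only the histone list of the p21 minus p16 contrast passed. The adjusted p of that test stands beside each list that passed with the preset correlation in the 9-library fit. Genes named in the text follow a rule set at the same time: a panel of 14 genes; the 6 largest changes in each direction among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups' libraries; and up to 4 called members, by lowest adjusted p, of each list that passed or had at least 3 called members. Any other list could give at most its most abundant member. With 3 libraries against 3, chance alone separates 10% of unchanged genes in this way.

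Replicate numbers in the titles are shared by the groups. The deviations of same-numbered p16 and control libraries from their group means correlated at 0.25, 0.11 and 0.55, and those of p21 and p16 libraries at 0.16, 0.29 and 0.48, so these numbers were taken to pair the samples on the evidence of the data alone, each value being above the limit of 0.1. That evidence is weak for p16 and control, where replicates 1 and 2 correlated better with another number (0.3). For p21 and control the values were not all above the limit. Numbers that pair p16 with both other groups would also pair p21 with control, so the rule does not settle the pairing. The main fit holds no replicate term, and results with the number as a block are given as an alternative.

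The edgeR test was tested on counts simulated from the real means, library sizes and dispersions with 200 changed genes. For p21 against control, over 14253 genes, it recovered 66% of genes changed 1.5-fold, 79% of those changed 2-fold and 88% of those changed 4-fold, and 6.02% of its calls were false. For p16 against control, over 14258 genes, these values were 68%, 73%, 92% and 4.38%. For p21 against p16, over 14263 genes, they were 68%, 78%, 96% and 5.33%.

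Alternatives fixed beforehand were the replicate number as a block, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, CPM of at least 1 in at least 3 libraries, library size alone, the compared groups alone, a 2-fold minimum, omission of Cdkn1a and Cdkn2a, and omission of each library in turn. Restriction to replicates 1 and 2 of each group, and a term for replicate 3, were added after sex-linked transcripts had been seen.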

Results

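Mouse embryonic fibroblasts were given p21 or p16 with a lentivirus, or the empty vector, and their transcriptomes were compared after 10 days. Both proteins inhibit cyclin-dependent kinases and can hold cells in the permanent arrest called senescence. They are encoded by Cdkn1a (p21) and Cdkn2a (p16). The title of the series concerns the secretome of p21-expressing cells and its recognition by immune cells. Each group held 3 libraries with 56.9 to 76.1 M counts per library, and 16523 to 16950 genes had at least 1 read in a library. Replicate 3 of each group differed from replicates 1 and 2 in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, stood at 397 CPM in control replicate 3, 158 CPM in p21 replicate 3 and 263 CPM in p16 replicate 3, and at no more than 1.34 CPM elsewhere. The Y-linked gene Ddx3y stood at 1.1, 10.8 and 1.27 CPM in those libraries and between 50.1 and 68.5 CPM in the rest.

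The overexpressed genes were read first. Cdkn1a (chromosome 17, 29090976 to 29100727, plus strand) stood at 366.2 ± 43.6 CPM in control, 1130 ± 76.4 CPM in p21 and 419.5 ± 22.3 CPM in p16 cells (SD, n = 3). It was 3.09-fold higher in p21 cells than in control cells (log2 fold change 1.63 ± 0.0891 SE, adjusted p = 8.05e-06) and did not pass between p16 and control cells (1.15-fold, adjusted p = 0.2). Cdkn2a (chromosome 4, 89274471 to 89294653, minus strand) stood at 63.08 ± 5.03 CPM in control, 95.58 ± 16.7 CPM in p21 and 1017 ± 64.6 CPM in p16 cells. It was 16.1-fold higher in p16 cells (adjusted p = 6.8e-07) and 1.52-fold higher in p21 cells (adjusted p = 0.0027). The 3 libraries of each overexpressing group lay above all control libraries for the gene they were given.

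**Figure D1:**
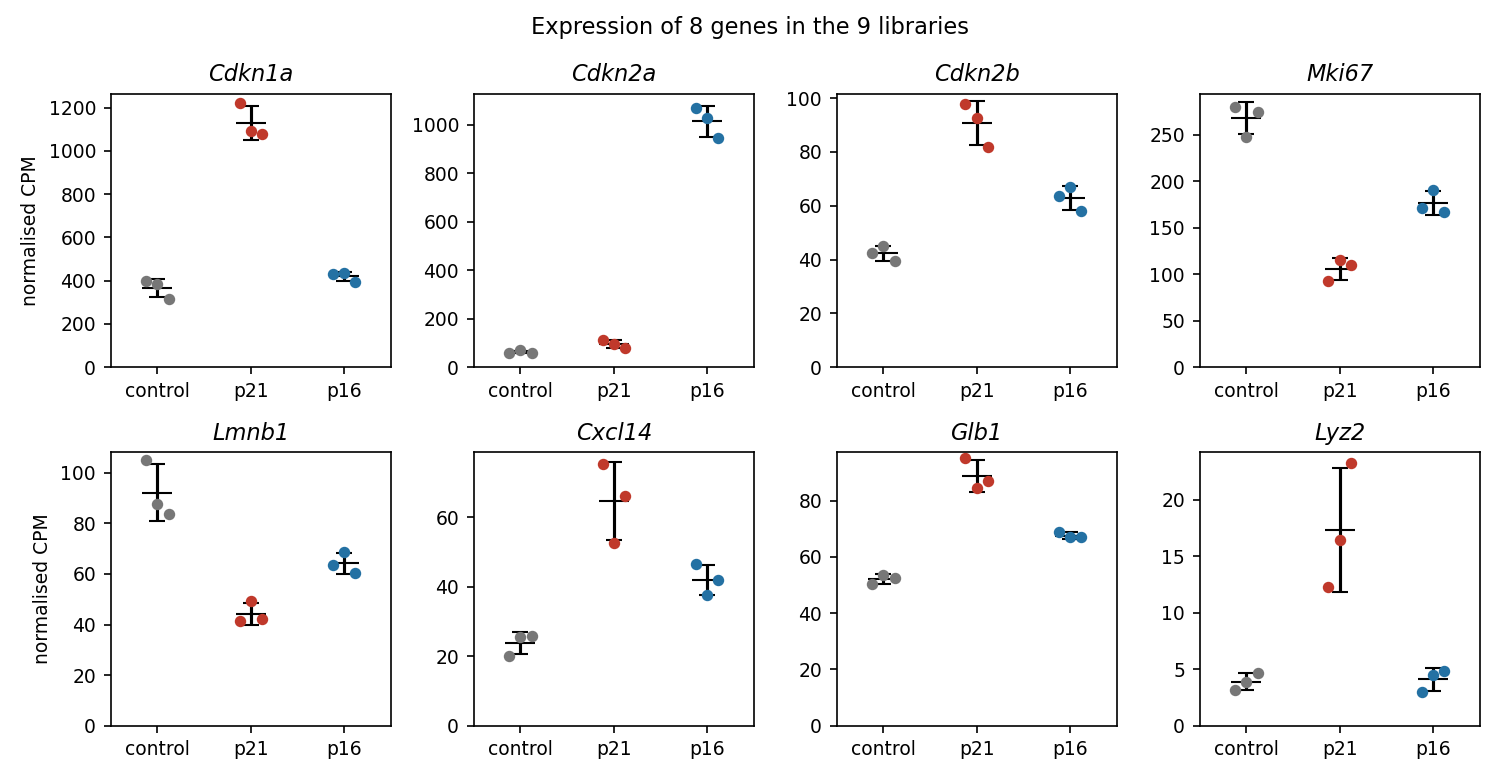
Normalised CPM (vertical axes, from 0) of 8 genes in control, p21 and p16 cells; coloured points are libraries, black bars the mean ± SD of 3 libraries. Cdkn1a is highest in p21 cells (1130 CPM), Cdkn2a in p16 cells (1017 CPM), and Mki67 is lower in both groups than in control cells (105.7 and 176.3 CPM against 267.8 CPM).

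The first comparison asked what p21 changed relative to the empty vector. Most genes tested for cell division fell in p21 cells, as did most of those for nuclear lamina and chromatin proteins, ribosomal proteins, cholesterol synthesis and the response to unfolded proteins. Most lysosome, protease and histone genes rose, and so did some growth factor, complement and p53 target genes. Mki67, a marker of cycling cells, was 2.53-fold lower (105.7 ± 11.8 against 267.8 ± 17.9 CPM, adjusted p = 1.35e-05), and Lmnb1, which encodes lamin B1, was 2.08-fold lower (adjusted p = 5.44e-05). Glb1, the lysosomal beta-galactosidase gene, was 1.7-fold higher (88.67 ± 5.66 against 52.16 ± 1.57 CPM, adjusted p = 1.54e-05). Of the 14572 genes tested, 2808 were higher and 3012 lower in p21 cells, 5820 in all, and 497 of the former and 282 of the latter changed at least 2-fold. Scaled by library size alone, 2465 were higher and 3450 lower, against 2900 and 2852 with DESeq2 size factors.

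All 32 mitosis genes fell (32 adjusted over the list alone, median log2 fold change -1.13, camera adjusted p = 3.31e-21; adjusted p = 0.28 with an estimated correlation). Among them, the kinesin gene Kif11 was 2.26-fold lower and Cenpa, which encodes the histone variant of centromeres, 2.28-fold lower. Of 32 DNA replication genes 29 fell (29 adjusted over the list alone, median -0.74, adjusted p = 6.06e-12; adjusted p = 0.36 with an estimated correlation). They include Uhrf1 (2.2-fold), Lig1, which encodes a DNA ligase (1.9-fold), and the helicase factor gene Cdc45 (1.92-fold). Of 24 genes for nuclear lamina and senescence chromatin, 21 fell (22 adjusted over the list alone, median -0.75, adjusted p = 1.94e-11; adjusted p = 0.28 with an estimated correlation). Hmgb2 was 2.26-fold and the condensin gene Smc4 2.07-fold lower. In the opposite direction to these lists, 13 of 21 replication-dependent histone genes rose (13 adjusted over the list alone, median 1.22, adjusted p = 1.18e-05; adjusted p = 0.093 with an estimated correlation). Hist1h3b was 7.84-fold higher, at 9.645 ± 1.28 against 1.228 ± 0.269 CPM, and Hist1h2bc, the more abundant, was 2.9-fold higher (93.55 ± 8.38 against 32.26 ± 1.72 CPM). Near-identical histone copies make single members uncertain.

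Of 28 lysosome genes 25 rose (27 adjusted over the list alone, median 0.57, adjusted p = 1.67e-13; adjusted p = 0.093 with an estimated correlation). Asah1, which encodes acid ceramidase, was 1.58-fold and the cholesterol carrier gene Npc2 1.59-fold higher. Of 25 genes for proteases and inhibitors 17 rose (17 adjusted over the list alone, median 0.66, adjusted p = 3.49e-05; adjusted p = 0.093 with an estimated correlation), among them the cathepsin genes Ctsd (2.2-fold), Ctsl (1.96-fold) and Ctsb (1.58-fold) and the metalloproteinase inhibitor gene Timp2 (2.05-fold, 2107 ± 64.3 against 1028 ± 45.6 CPM). Mmp3, a matrix metalloproteinase gene, was 3.41-fold higher but at only 2.923 ± 0.835 CPM (adjusted p = 0.00271). Of 25 growth factors and binding proteins 9 rose (9 adjusted over the list alone, adjusted p = 0.0143; adjusted p = 0.28 with an estimated correlation): Igfbp3 was 3.09-fold, Gas6 2.28-fold and Grn, which encodes progranulin, 1.5-fold higher. Of 15 complement genes 7 rose (8 adjusted over the list alone, adjusted p = 0.0158; adjusted p = 0.43 with an estimated correlation). The complement and growth factor calls were lost without control replicate 1 (adjusted p = 0.0703 and 0.069) or without p21 replicate 3 (adjusted p = 0.0728 and 0.0578). Markers of macrophages moved with these lists: 12 of 17 rose (13 adjusted over the list alone, median 1.51, adjusted p = 0.000144; adjusted p = 0.36 with an estimated correlation). Their levels were low, with Lyz2, the lysozyme gene of macrophages, at 17.31 ± 5.53 against 3.883 ± 0.757 CPM (4.45-fold) and Ptprc, a leukocyte surface marker, at 0.7464 ± 0.156 against 0.247 ± 0.0695 CPM.

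The list of the senescence secretome linked to NF-kB did not move as a list. It joins inflammatory secreted factors with genes whose products are not secreted, such as Nfkb1. Of its 21 tested genes, 5 rose and 4 fell (5 and 5 adjusted over the list alone, adjusted p = 0.878). Whether its secreted members alone moved together was not tested. The monocyte chemoattractant gene Ccl2 was 1.3-fold higher (37.27 ± 2.41 against 28.57 ± 0.979 CPM, adjusted p = 0.00128) and the related Ccl7 1.83-fold higher, whereas Nfkb1 was 1.46-fold lower. Il6 was 1.8-fold higher at 2.2 ± 0.915 CPM (adjusted p = 0.0335), a call lost without p21 replicate 3 (adjusted p = 0.0995), control replicate 1 (adjusted p = 0.0613) or control replicate 2 (adjusted p = 0.11). Cxcl1 (adjusted p = 0.48) did not pass. Of 12 other chemokines 4 rose (2 adjusted over the list alone, adjusted p = 0.497). Cxcl14 rose 2.71-fold, from 23.85 ± 3.21 to 64.63 ± 11.4 CPM (adjusted p = 7.07e-05). Interferon response genes (1 higher and 3 lower of 22, adjusted p = 0.878) and antigen presentation genes (2 higher and 2 lower of 18, adjusted p = 0.62) did not pass as lists.

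Of 26 p53 targets 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.175, adjusted p = 0.00745; adjusted p = 0.36 with an estimated correlation). Rrm2b was 1.57-fold and Gdf15 1.51-fold higher, Bbc3, an apoptosis gene, 1.37-fold lower, and Trp53 itself 1.21-fold lower (adjusted p = 0.00592). Every one of 29 ribosomal protein genes fell, by small amounts (29 adjusted over the list alone, median -0.28, adjusted p = 6.06e-12; adjusted p = 0.28 with an estimated correlation). Rpl3 was 1.32-fold lower. Of 22 cholesterol synthesis genes 16 fell and 1 rose (17 and 2 adjusted over the list alone, median -0.23, adjusted p = 0.000131; adjusted p = 0.36 with an estimated correlation). Fdps was 1.31-fold and Lss 1.39-fold lower. Of 24 genes of the unfolded protein and amino acid stress list 14 fell and 2 rose (17 and 2 adjusted over the list alone, adjusted p = 0.000246; adjusted p = 0.28 with an estimated correlation): Psat1, of serine synthesis, was 1.8-fold lower, the amino acid transporter gene Slc7a5 2-fold lower and the chaperone gene Hspa5 1.29-fold lower. Lists that did not pass were TGF-beta and BMP (8 higher, 2 lower of 25, adjusted p = 0.0752), contractile cytoskeleton (11 higher, 4 lower of 20, adjusted p = 0.0685), immediate early genes (2 higher, 9 lower of 21, adjusted p = 0.0685), matrix glycoproteins (10 higher, 6 lower of 32, adjusted p = 0.497) and collagens (5 higher, 2 lower of 19, adjusted p = 0.684). The TGF-beta and contractile lists passed with a replicate 3 term (adjusted p = 0.0463 and 0.028), with replicates 1 and 2 of each group (0.0473 and 0.0108) and with fry (0.00745 and 0.0185). The contractile list also passed without p21 replicate 3 (0.0144), and the immediate early list without p21 replicate 1 (0.0399) and with fry (0.00634). Within them the smooth muscle myosin gene Myh11 was 2.38-fold and the basement membrane collagen gene Col4a1 1.45-fold higher, and the matrix gene Fbln1 was 2.11-fold lower. NRF2 antioxidant (6 higher, 5 lower of 21, adjusted p = 0.497), BCL2 family (5 higher, 1 lower of 14, adjusted p = 0.589), CDK inhibitor (6 higher, 8 lower of 18, adjusted p = 0.921) and glycolysis genes (3 higher, 3 lower of 26, adjusted p = 0.838) did not pass either, though Cdkn2b, the neighbour of Cdkn2a, was 2.14-fold and the haem oxygenase gene Hmox1 2.65-fold higher. The median and the camera direction had opposite signs for the NF-kB, collagen, CDK inhibitor and endothelial lists, and the mean did so for matrix glycoproteins. Markers of other cell types did not pass: skeletal muscle (3 higher of 10, adjusted p = 0.0711), pericytes (3 higher of 8, adjusted p = 0.193), cartilage and bone (2 higher, 3 lower of 11, adjusted p = 0.684), endothelium (1 higher, 2 lower of 11, adjusted p = 0.946), epithelium (1 higher, 1 lower of 6, adjusted p = 0.878) and nerve (2 higher, 1 lower of 8, adjusted p = 0.878). With fry the skeletal muscle (adjusted p = 0.00025) and BCL2 family lists (0.00304) passed. The adipocyte list had 4 tested markers, 1 of them lower, too few for a list test.

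Among genes with a mean log2 CPM of at least 2 and no overlap between libraries, the largest increases were those of Hist1h3b and Hist1h2ab (5.99-fold), Lce1h of the epidermal cornified envelope (5.86-fold), Parm1 (4.91-fold, 18.53 ± 1.03 against 3.775 ± 0.0769 CPM), Serpinb9b (4.78-fold) and Lyz2. By the same limits, the largest falls were in the fibrillin gene Fbn2 (3.33-fold), the urea transporter gene Slc14a1 (3.16-fold), Gli2, a transcription factor of Hedgehog signalling (3.06-fold), Abi3bp (3.05-fold), the imprinted gene Dlk1 (2.81-fold, 51.36 ± 10.6 against 144.1 ± 52.2 CPM) and Fndc4 (2.68-fold).

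The next comparison asked the same of p16. The changes were smaller. Most mitosis and ribosomal protein genes fell, with some of those for DNA replication, nuclear lamina and chromatin and a few of the unfolded protein response. Some lysosome genes rose, with a few protease, growth factor, p53 target, contractile and histone genes. Mki67 was 1.52-fold lower than in control cells (176.3 ± 12.9 against 267.8 ± 17.9 CPM, adjusted p = 0.00774), Lmnb1 1.43-fold lower (adjusted p = 0.0176) and Glb1 1.3-fold higher (adjusted p = 0.00745). Of 14572 genes, 520 were higher and 532 lower in p16 cells, 1052 in all, and only 61 and 9 of these changed at least 2-fold.

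Of the 32 mitosis genes 20 fell (30 adjusted over the list alone, median -0.36, adjusted p = 5.54e-16; adjusted p = 0.34 with an estimated correlation). The cyclin gene Ccna2 was 1.44-fold lower. Of 32 DNA replication genes 12 fell (24 adjusted over the list alone, median -0.36, adjusted p = 1.92e-10; adjusted p = 0.45 with an estimated correlation). Uhrf1 was 1.48-fold lower. Nuclear lamina and chromatin genes fell in 12 of 24 cases (20 adjusted over the list alone, adjusted p = 1.25e-10; adjusted p = 0.32 with an estimated correlation). Hmgb2 was 1.57-fold lower. Ribosomal protein genes fell in 15 of 29 cases (28 adjusted over the list alone, median -0.16, adjusted p = 6e-14; adjusted p = 0.32 with an estimated correlation). Of 24 unfolded protein and amino acid stress genes 3 fell (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.000996; adjusted p = 0.32 with an estimated correlation). Lysosome genes rose in 13 of 28 cases (18 adjusted over the list alone, median 0.21, adjusted p = 2.33e-10; adjusted p = 0.23 with an estimated correlation). Asah1 rose by 1.25-fold. Proteases and inhibitors rose in 5 of 25 cases (7 adjusted over the list alone, median 0.33, adjusted p = 7.78e-07; adjusted p = 0.087 with an estimated correlation). Ctsd was 1.4-fold and Timp2 1.32-fold higher. Growth factors rose in 3 of 25 (5 adjusted over the list alone, adjusted p = 0.000461; adjusted p = 0.23 with an estimated correlation). Gas6 was 1.83-fold higher. Of 26 p53 targets 4 rose (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00562; adjusted p = 0.45 with an estimated correlation). Histone genes rose in 6 of 21 cases (7 adjusted over the list alone, median 0.13, adjusted p = 0.0101; adjusted p = 0.32 with an estimated correlation), Hist1h3b by 2.36-fold and Hist1h2bc by 1.64-fold. This call was lost without p16 replicate 2 (adjusted p = 0.071) or 3 (adjusted p = 0.0702).

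In p16 cells a few genes of contractile fibres and of the matrix also rose. Of 20 contractile genes 4 were higher (7 adjusted over the list alone, adjusted p = 0.0021; adjusted p = 0.45 with an estimated correlation). Myh11 was 1.65-fold and the intermediate filament gene Des 1.76-fold higher. Of 8 pericyte and smooth muscle markers 3 rose (3 adjusted over the list alone, adjusted p = 0.00562; adjusted p = 0.45 with an estimated correlation). Rgs5 rose by 1.84-fold. The list call was lost without control replicate 1 (adjusted p = 0.0754). Of 32 matrix glycoproteins 6 rose (7 adjusted over the list alone, adjusted p = 0.0274; adjusted p = 0.57 with an estimated correlation). The fibronectin gene Fn1 rose by 1.41-fold (17570 ± 1720 against 12450 ± 2150 CPM). That list no longer passed with the replicate block (adjusted p = 0.0664), without control replicate 1 (adjusted p = 0.405, its median then -0.011), without p16 replicate 3 (adjusted p = 0.172) or with fry (adjusted p = 0.189). Of 19 collagens 4 rose (5 adjusted over the list alone, adjusted p = 0.0617), among them Col4a1 (1.45-fold) and Col4a2 (1.43-fold). The collagen list passed with replicates 1 and 2 of each group (adjusted p = 0.0376) and without control replicate 2 (0.0357), control replicate 3 (0.00214), p16 replicate 1 (0.043) or p16 replicate 2 (0.0264). The complement list passed (median 0.39, adjusted p = 0.0205; adjusted p = 0.48 with an estimated correlation) with 0 of 15 genes called by edgeR, 4 higher at an unadjusted p under 0.05 and 2 higher by DESeq2. Without control replicate 1 or p16 replicate 3, or with fry, it did not pass (adjusted p = 0.145, 0.168 and 0.162).

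Secreted factors of p16 cells showed few calls. Cxcl14 was 1.76-fold higher (41.93 ± 4.41 against 23.85 ± 3.21 CPM, adjusted p = 0.0124; 0.0511 without p16 replicate 1), in a chemokine list with 2 of 12 higher (2 adjusted over the list alone, adjusted p = 0.182). That list passed with replicates 1 and 2 of each group (adjusted p = 0.0471) and without control replicate 3 (0.0274) or p16 replicate 1 (0.0479). Il6 (2.02-fold, adjusted p = 0.0541), Ccl2 (1.14-fold, adjusted p = 0.0996), Mmp3 (adjusted p = 0.4) and Cxcl1 (adjusted p = 0.95) did not pass. Il6 was nevertheless higher in each p16 library than in the control of the same number (2.23, 2.45 and 2.66 against 1.23, 0.962 and 1.44 CPM). So was Ccl2 (34.6, 32.4 and 30.8 against 27.5, 29.6 and 28.6 CPM), whereas Mmp3 and Cxcl1 went both ways. The NF-kB list did not pass either (adjusted p = 0.542). In it edgeR called 0 of 21 genes, 5 were higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher. Macrophage markers had a median log2 fold change of -0.26 (adjusted p = 0.266), with Lyz2 at 4.113 ± 1.01 CPM. Their mean log2 CPM was lower in each p16 library than in the control of the same number (-1.52, -0.949 and -0.565 against -1.08, -0.677 and -0.515). Without p16 replicate 3 the list was lower (adjusted p = 0.0434). Cholesterol synthesis genes had a median of 0.022 (1 of 22 higher, adjusted p = 0.458). Other lists that did not pass were TGF-beta and BMP (2 higher, 2 lower of 25, adjusted p = 0.297), interferon response (adjusted p = 0.677), antigen presentation (adjusted p = 0.749), glycolysis (adjusted p = 0.803), NRF2 antioxidant (adjusted p = 0.803), CDK inhibitors (adjusted p = 0.803), BCL2 family (adjusted p = 0.353) and immediate early genes (adjusted p = 0.119). Markers of skeletal muscle (2 of 10 higher, adjusted p = 0.266), endothelium (adjusted p = 0.72), epithelium (adjusted p = 0.677), nerve (adjusted p = 0.803) and cartilage and bone (adjusted p = 0.582) did not pass either. The immediate early list passed without p16 replicate 1 (adjusted p = 0.0479), and the CDK inhibitor (0.0151), BCL2 family (0.0229) and skeletal muscle lists (0.0278) passed with fry. For the NF-kB and collagen lists the median was negative and the camera direction upward.

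After Cdkn2a, the largest increases without overlap, at a mean log2 CPM of at least 2, were those of Parm1 (2.83-fold, 10.67 ± 0.423 against 3.775 ± 0.0769 CPM), the endothelial receptor gene Notch4 (2.8-fold), the choline transporter gene Slc5a7 (2.54-fold), Hist1h2ab (2.43-fold) and Hist1h3b. By the same limits, the largest decreases were those of Enpp2, which encodes autotaxin (2.97-fold), the mesothelin gene Msln (2.47-fold, 4.412 ± 0.281 against 10.91 ± 0.938 CPM), the interleukin 33 receptor gene Il1rl1 (2.21-fold), Abi3bp (1.97-fold), Fndc4 (1.74-fold) and Runx3 (1.71-fold). Some of these calls ended without 1 library. Without p16 replicate 2, the adjusted p was 0.0547 for Enpp2, 0.0958 for Il1rl1, 0.0713 for Runx3 and 0.13 for Fn1. Without p16 replicate 3, it was 0.0592 for Lmnb1, 0.0647 for Il1rl1 and 0.102 for Fn1, and without p16 replicate 1 it was 0.066 for Lmnb1, 0.0507 for Enpp2, 0.0547 for Runx3 and 0.053 for Fn1. Without control replicate 2, it was 0.0663 for Il1rl1 and 0.0836 for Fn1. With the replicate number as a block 2473 genes were called (1252 higher, 1221 lower), with DESeq2 1808, with the compared groups alone 555 and, scaled by library size alone, 444 higher against 683 lower. The count was 375 without control replicate 2, 284 without p16 replicate 1, 222 without p16 replicate 2, 425 without p16 replicate 3 and 593 with replicates 1 and 2 of each group.

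**Figure D2:**
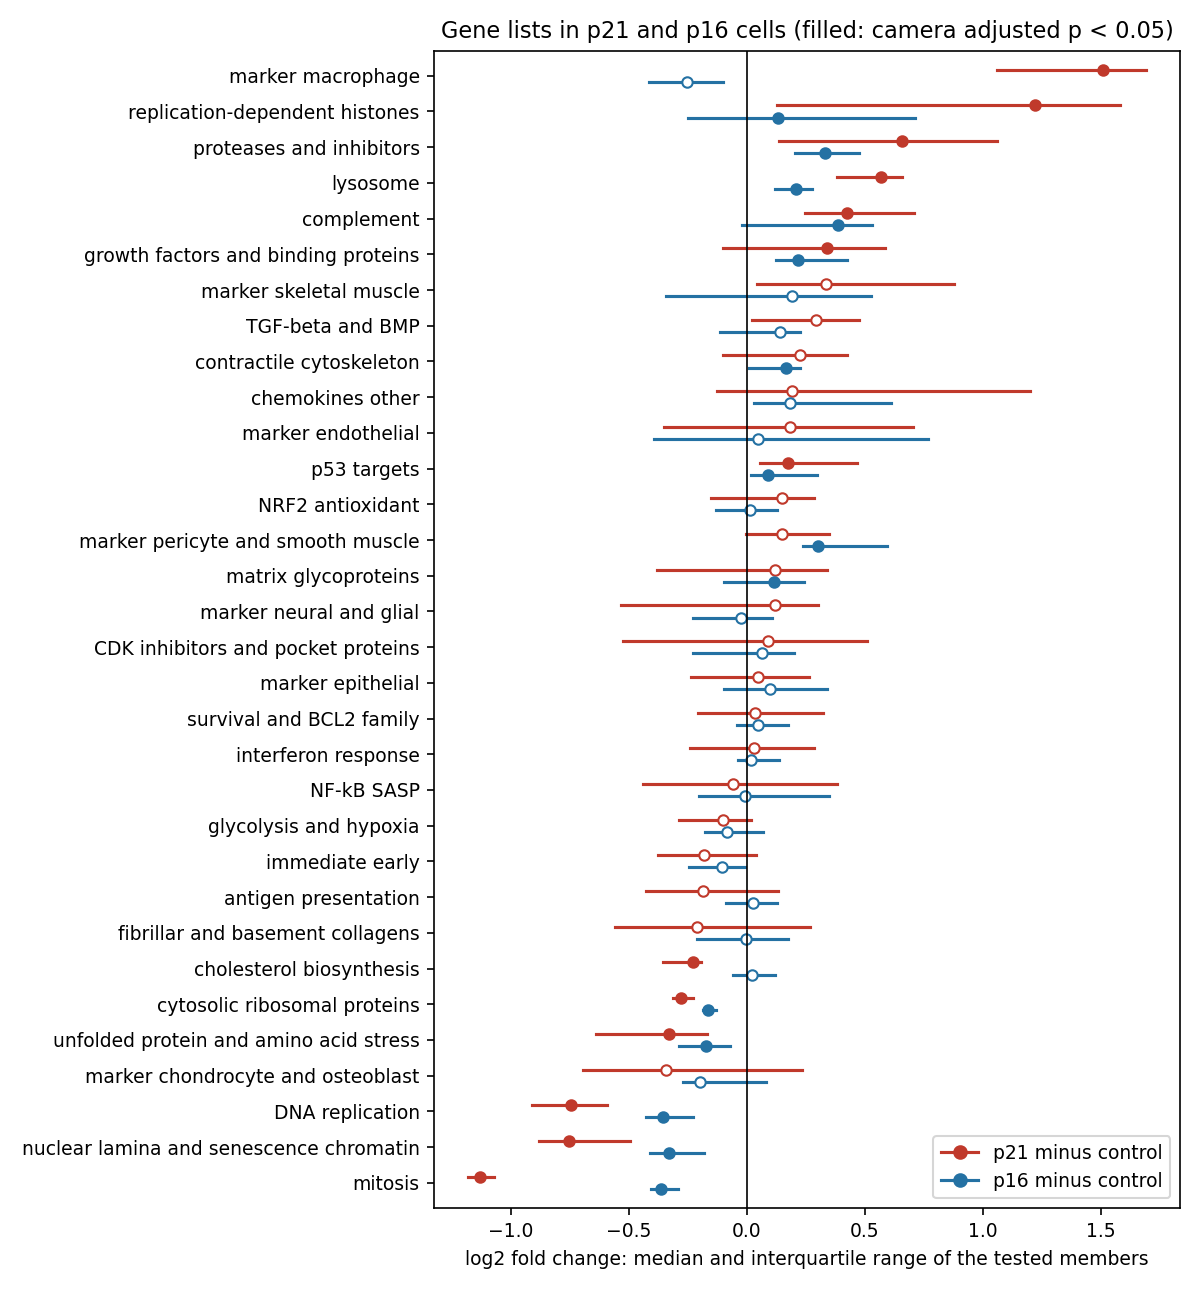
Median log2 fold change (horizontal axis, points) and interquartile range (lines) of the tested members of each gene list, in p21 (red) and p16 (blue) cells relative to control cells; filled points passed camera at an adjusted p under 0.05 with the preset correlation. The mitosis list lies at -1.13 in p21 and -0.36 in p16 cells, the lysosome list at 0.57 and 0.21, and macrophage markers at 1.51 and -0.26.

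The direct comparison asked where p21 and p16 cells differ. Most genes tested for cell division, cholesterol synthesis and nuclear lamina and chromatin were lower in p21 than in p16 cells, with a few for ribosomal proteins and the unfolded protein response. Most lysosome genes and macrophage markers were higher, with some histone and protease genes. Mki67 was 1.67-fold lower in p21 cells (105.7 ± 11.8 against 176.3 ± 12.9 CPM, adjusted p = 0.00142), Lmnb1 1.45-fold lower (adjusted p = 0.00882) and Glb1 1.31-fold higher (adjusted p = 0.00254). Of 14572 genes, 902 were higher and 968 lower in p21 cells, 1870 in all, with 109 and 13 changed at least 2-fold.

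All 32 mitosis genes were lower (32 adjusted over the list alone, median -0.77, adjusted p = 1.27e-28; adjusted p = 0.23 with an estimated correlation). Cenpa was 1.79-fold and Kif11 1.71-fold lower. Of 32 DNA replication genes 20 were lower (27 adjusted over the list alone, median -0.40, adjusted p = 7.72e-12; adjusted p = 0.44 with an estimated correlation), and of 24 nuclear lamina and chromatin genes 18 (20 adjusted over the list alone, adjusted p = 7.72e-12; adjusted p = 0.24 with an estimated correlation), such as Smc4, 1.6-fold. Of 22 cholesterol synthesis genes 15 were lower (19 adjusted over the list alone, median -0.27, adjusted p = 3.91e-10; adjusted p = 0.23 with an estimated correlation). Idi1 was 1.36-fold and Fdps 1.29-fold lower. Of 29 ribosomal protein genes 6 were lower (17 adjusted over the list alone, adjusted p = 1.93e-07; adjusted p = 0.46 with an estimated correlation), and of 24 unfolded protein and amino acid stress genes 5 were lower and 1 higher (7 and 2 adjusted over the list alone, adjusted p = 0.00509; adjusted p = 0.37 with an estimated correlation). Psat1 was 1.51-fold lower. Lysosome genes were higher in 19 of 28 cases (24 adjusted over the list alone, median 0.34, adjusted p = 3.65e-15; adjusted p = 0.11 with an estimated correlation). Psap, the gene for prosaposin, was 1.34-fold higher (1221 ± 49.4 against 913.5 ± 18.7 CPM). Of 25 proteases and inhibitors 8 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.00509; adjusted p = 0.23 with an estimated correlation). Ctsl and Ctsd were each 1.57-fold higher. Histone genes were higher in 10 of 21 cases (13 adjusted over the list alone, median 0.82, adjusted p = 1.7e-09; adjusted p = 0.044 with an estimated correlation). Hist1h3b was 3.32-fold and Hist1h4h 2.85-fold higher. Of 17 macrophage markers 11 were higher (14 adjusted over the list alone, median 1.93, adjusted p = 1.93e-09; adjusted p = 0.23 with an estimated correlation). Lyz2 was 4.19-fold and the mannose receptor gene Mrc1 3.07-fold higher. Of 10 skeletal muscle markers 2 were higher (3 adjusted over the list alone, adjusted p = 0.0391; adjusted p = 0.23 with an estimated correlation), the actin gene Acta1 by 1.74-fold and Des by 1.37-fold (adjusted p = 0.0306, and 0.0506 to 0.127 without p21 replicate 1 or 2 or any p16 library). The list call was lost with the replicate block (adjusted p = 0.0772) and without p21 replicate 1 (adjusted p = 0.0806), p21 replicate 2 (adjusted p = 0.0555), p16 replicate 1 (adjusted p = 0.101) or p16 replicate 3 (adjusted p = 0.0708).

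Cxcl14 was 1.54-fold higher in p21 than in p16 cells (adjusted p = 0.0193; 0.085 without p21 replicate 1, 0.0738 without p16 replicate 2, 0.0586 without p16 replicate 3) and Mmp3 2.38-fold higher (adjusted p = 0.0368; 0.0765 to 0.126 without p21 replicate 1 or 2 or any p16 library). Ccl2 (adjusted p = 0.077), Il6 (adjusted p = 0.737), Gdf15 (adjusted p = 0.439), Cxcl1 (adjusted p = 0.644) and Trp53 (adjusted p = 0.253) did not pass, and Cdkn2b was 1.44-fold higher (adjusted p = 0.00386). Lists of p53 targets (1 higher, 1 lower of 26, adjusted p = 0.265), NF-kB factors (1 higher, 1 lower of 21, adjusted p = 0.83), other chemokines (1 higher of 12, adjusted p = 0.873), growth factors (2 higher of 25, adjusted p = 0.301), TGF-beta and BMP (3 higher, 1 lower of 25, adjusted p = 0.265), collagens (1 lower of 19, adjusted p = 0.632), matrix glycoproteins (2 higher, 3 lower of 32, adjusted p = 0.869), contractile (2 higher, 3 lower of 20, adjusted p = 0.83) and CDK inhibitor genes (2 higher, 6 lower of 18, adjusted p = 0.328; 0.00779 with fry) did not pass. Complement (adjusted p = 0.221) passed only with the replicate block (adjusted p = 0.0363), without p16 replicate 3 (adjusted p = 0.0202) or without p21 replicate 2 (adjusted p = 0.0367). Interferon response (adjusted p = 0.953), antigen presentation (adjusted p = 0.301), glycolysis (adjusted p = 0.975), NRF2 antioxidant (adjusted p = 0.301), BCL2 family (adjusted p = 0.829) and immediate early genes (adjusted p = 0.24) did not pass, nor did markers of endothelium (adjusted p = 0.657), epithelium (adjusted p = 0.982), nerve (adjusted p = 0.783), cartilage and bone (adjusted p = 0.953) and pericytes (adjusted p = 0.83). The interferon and epithelial lists had a median of opposite sign to the camera direction.

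Besides Cdkn1a, the largest excesses in p21 over p16 cells without overlap, at a mean log2 CPM of at least 2, were those of Lyz2, Hist1h3b, the apolipoprotein gene Apoe (2.65-fold; adjusted p = 0.0678 without p16 replicate 1 and 0.0658 without p16 replicate 2), Tmem151a (2.56-fold) and Hist1h2ab (2.46-fold). Besides Cdkn2a (10.6-fold lower), large deficits included those of Fndc1 (2.66-fold), Gli2 (2.13-fold), Dlk1 (1.99-fold) and the heat shock gene Hspa1a (1.96-fold, 6.515 ± 0.301 against 12.77 ± 0.624 CPM). Dlk1 lost its call without any of the p21 or p16 libraries (adjusted p = 0.0516 to 0.172), and Gli2 did so except without p21 replicate 3 (adjusted p = 0.0786 to 0.167). With the replicate number as a block 3496 genes were called (1715 higher, 1781 lower). The count was 600 without p21 replicate 1, 922 without p21 replicate 2, and 789, 875 and 959 without p16 replicates 1, 2 and 3.

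Most p16 calls were shared by p21 cells, but most p21 calls were not shared by p16 cells. A p21 call without a p16 call does not show a change particular to p21, since p16 changes were smaller. Among the genes compared, 81.6% had the same sign in both comparisons, against a mean of 66.5% in simulated unchanged groups that share the controls. Of 1052 p16 calls and 5820 p21 calls, 1023 genes were called in the same direction in both. Leaving out Cdkn1a and Cdkn2a, these were 500 higher and 522 lower genes, 97.2% of the 1051 p16 calls, where independent lists of those sizes would share 100 higher and 110 lower genes. Both comparisons use the same controls, which cannot be split because there are 3, so part of the excess may come from them. How many shared calls they would give when both groups change was not tested. By edgeR 0 genes were called in opposite directions, against 9 at an unadjusted p under 0.05 in both comparisons and 1 by DESeq2. Across genes, the log2 fold changes correlated at 0.737 (simulated mean 0.493), genes not being independent replicates, and their covariance was 0.131 against a simulated mean of 0.0258, a difference of 0.105. The shared count was 2317 with the replicate block, 367 without control replicate 2, 273, 219 and 418 without p16 replicates 1, 2 and 3, and 570 with replicates 1 and 2 of each group.

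**Figure D3:**
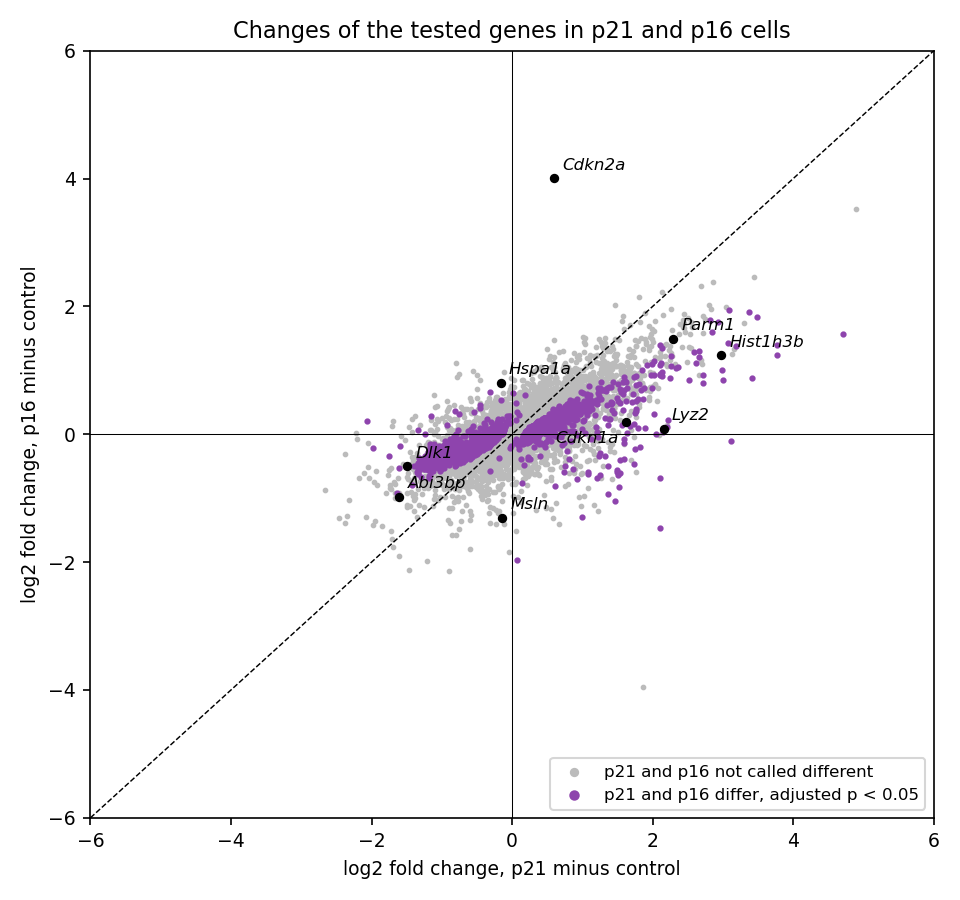
Log2 fold change of each of 14572 genes in p21 cells (horizontal axis) and p16 cells (vertical axis) relative to control cells; purple points differ between p21 and p16 cells at an adjusted p under 0.05, black points are named genes, and the dashed line marks equal change. Most changed genes lie along a slope shallower than the dashed line; Cdkn2a (log2 fold change 4.01 in p16 cells), Hspa1a and Msln stand apart.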

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

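The tests of macrophage markers and of sex-linked transcripts were chosen after those patterns had been seen. The tests of the shared p21 and p16 response and of other splits of the libraries were set before their results.

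The effects of p21 and p16 differed for 1870 genes by the contrast between them. The same contrast differed for 11 gene lists, given here by the median log2 difference, p21 minus p16. Medians were negative for mitosis (-0.771), nuclear lamina and chromatin (-0.423), DNA replication (-0.398), cholesterol synthesis (-0.273), unfolded protein and amino acid stress (-0.171) and ribosomal proteins (-0.117). Medians were positive for macrophage markers (1.93), histones (0.824), skeletal muscle markers (0.398), lysosome (0.336) and proteases and inhibitors (0.279). With an estimated correlation only the histone list kept its call (adjusted p = 0.044). Of genes with a called difference, 164 called in p21 cells had the opposite sign in p16 cells, where none of them was called. Of p16 calls with a called difference, 3 had the opposite sign in p21 cells and were singled out after their values were seen. These were Hspa1a (0.807 in p16 and -0.163 in p21 cells), Gdf5 (-1.96 and 0.072) and Anxa8 (-0.393 and 0.221), none of which passed in p21 cells. The Gdf5 calls rest on under 1 CPM: in p16 cells the call ended without control replicate 1, 2 or 3 (adjusted p = 0.0661, 0.0836 and 0.0692) or p16 replicate 2 or 3 (0.0629 and 0.0843) and with the compared groups alone (0.0887). The Gdf5 difference ended without p21 replicate 1 or 2 (0.0817 and 0.0588) or p16 replicate 3 (0.0581).

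Most p16 changes resembled smaller p21 changes, with a scaling of 0.441 after the covariance and variance of simulated unchanged groups were removed. Whether shared controls alone gave this resemblance could not be decided. The covariance of the fold changes was 0.131, above the highest of 50 simulated sets (0.0293). It was also above the variance of the control mean taken from the control libraries themselves (0.0326, a limit added after the result). Yet genes of a list deviated together (estimated correlation 0.7 for mitosis), whereas the simulation drew each gene on its own. The second limit rests on the few control libraries. Neither limit therefore bounds a control deviation shared by many genes. A common factor for every gene is argued against by 2 genes that departed from it, each at an adjusted p of 0.000711. These were Msln (log2 fold change -0.143 in p21 and -1.31 in p16 cells) and Hspa1a (-0.163 and 0.807). At most 1 gene departed in 20 simulated sets. The bound written beforehand also counts against the factor. A rule loosened after the result was seen left it open, because the margin of 1 gene lies inside counting error (0.24 to 7.2, 95% interval). Whether such a factor holds for the other genes remains open. Lists that departed from it with the preset correlation were cholesterol synthesis (adjusted p = 1.53e-11), macrophage markers (1.61e-11), mitosis (2.11e-08), ribosomal proteins (0.000155), pericyte markers (0.00129), contractile genes (0.00169), collagens (0.00288), matrix glycoproteins (0.00691), growth factors (0.0287) and histones (0.0352), none of which did so with an estimated one (adjusted p of 0.55 to 0.68).

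Macrophage markers were higher in p21 libraries. A single contaminated library is argued against, because the mean marker level of all 3 p21 libraries (0.164, 0.585 and 0.939 log2 CPM) lay above the highest control (-0.515), though the level climbed from replicate 1 to 3 in every group. A lower share of fibroblasts that raised every other cell type was tested too. The 29 markers of endothelium, epithelium, nerve and fat had a median log2 fold change of 0.11 (bootstrap 95% interval -0.334 to 0.191). For 17 macrophage markers it was 1.51 (1.06 to 1.69). These intervals resample markers, not libraries. The other markers thus rose less as a set, but the test cannot decide on a lower share, since those cell types may have been absent from the cultures. Skeletal muscle, pericyte, and cartilage and bone lists were left out of it (medians 0.336, 0.151 and -0.342). Macrophages as the source of the lysosome rise are argued against for p16 cells, where 27 lysosome genes gained 685 CPM in sum and the markers changed by -1.68 CPM. In p21 cells the markers gained 25 CPM, 1.3% of the 1920 CPM gained by the lysosome genes. That ratio does not give the part of the p21 rise that macrophages could supply, since no macrophage library was compared. Whether a small number of macrophages or expression by fibroblasts accounts for the markers stays open, as does the p21 treatment as their cause.

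In p21 replicate 3, Y-linked transcripts lay between the levels of the other libraries. The shares of the mean of p21 replicates 1 and 2 were 17.7% for Ddx3y, 20% for Eif2s3y, 21.5% for Kdm5d and 25.4% for Uty, with a mean of 21.2%, against means of 2.34% in control replicate 3 and 1.73% in p16 replicate 3. A swapped label is argued against, since the highest share was 25.4% and Xist stood at 158 CPM. Male cells or RNA mixed into this library are a candidate explanation, which cannot be told apart from others because the shares differed among the genes by 1.43-fold, more than the 1.22-fold spread of such ratios between p21 replicates 1 and 2 but close to the 1.42-fold spread in control cells. Without that library, 5387 genes were called for p21 against control and 1790 for p21 against p16.

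With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so no share can decide whether chance is excluded. The real split was the 1 split with as many calls in each comparison. It gave 5820, 1052 and 1870 genes for p21 against control, p16 against control and p21 against p16, and the highest of the other splits gave 0 genes by edgeR in each, with at most 2099, 2508 and 1211 genes at an unadjusted p under 0.05. For the paired comparisons, the other splits that part every replicate number also gave 0. Every other split mixes the groups, so a real effect widens its spread, and 0 calls there do not measure chance.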

How the results depend on the processing

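The replicates 1 and 2 restriction and the replicate 3 term were chosen after seeing the data. Of 6649 values of single genes and lists under an alternative, 6174 stayed on their side of the threshold, 401 lost a call and 74 gained one. No called gene or list turned its test direction (0 values), but the median of the p16 matrix glycoprotein list turned to -0.011 without control replicate 1. For p21 against control, 5820 genes became 779 with a 2-fold minimum, lay between 4224 and 5788 without any single library, and between 5076 and 7333 in the other settings. Its libraries were taken to share only a number, since replicate 2 fell below the limit of 0.1 (correlations 0.18, 0.025 and 0.49, only replicate 3 matching its own number best). That does not show them to be unpaired. With the number as a block 7241 genes were called, and the TGF-beta and contractile lists passed (adjusted p = 0.0382 and 0.0369). For p16 against control, 1052 became 2473 with the replicate block, 2645 with the replicate 3 term, 1808 with the DESeq2 Wald test, 555 with the compared groups alone, 593 with replicates 1 and 2, 70 with a 2-fold minimum, and 222 to 873 without a single library. For p21 against p16, 1870 became 3496 with the block, 3622 with the replicate 3 term, 122 with a 2-fold minimum and 600 to 1790 without a single library. The shared 1023 genes became 2317 with the block, 570 with replicates 1 and 2, 60 with a 2-fold minimum and 219 to 910 without a single library. Gene lists passing (13, 14 and 11) became 0, 0 and 1 with an estimated correlation (3, 4 and 6 at an unadjusted p under 0.05) and stayed within 10 to 17 without a single library. The block changed no list call for the paired comparisons beyond those named with the results. The 2-fold losses follow from a stricter rule. Losses with fewer libraries do not follow from sample number alone. For p21 against p16, 1804 genes were called with replicates 1 and 2 of each group, against 600 without p21 replicate 1. The cause of these and the other changes was not tested. Named calls that held under every alternative run for single genes, which leaves out the 2-fold minimum, numbered 117 of 133, 40 of 76 and 48 of 73. Genes under about 1 CPM, among them Cxcl1 and, in control cells, most macrophage markers, rest on few reads.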

Other observations

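The tests of the 3 lists below were chosen after single members had been seen among the largest changes. Their p-values therefore do not test those patterns independently. Of 17 genes of the epidermal barrier and of desmosomes, which skin epithelium uses, 9 were higher and 1 lower in p21 cells (median log2 fold change 0.722, camera adjusted p = 0.0134; adjusted p = 0.47 with an estimated correlation). The desmosome gene Dsp went from 3.406 ± 0.798 to 14.97 ± 3.2 CPM (SD, n = 3, adjusted p = 0.000121), Jup from 105.3 ± 9.09 to 173.6 ± 26.3 CPM and the cornified envelope gene Sprr1a from 2.554 ± 0.603 to 6.758 ± 0.596 CPM. In p16 cells 4 of 17 were higher (adjusted p = 0.0322; adjusted p = 0.49 with an estimated correlation), and 5 of 17 were higher in p21 than in p16 cells (adjusted p = 0.0318; adjusted p = 0.67 with an estimated correlation). Epithelial markers did not pass in either group.

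Of 10 Hedgehog signalling genes 5 fell in p21 cells (median -0.412, adjusted p = 0.0644), Gli2, Gli3, Hhip, Smo and Gas1, so the list did not pass. In p16 cells the median was -0.145 (adjusted p = 0.0713). Imprinted growth genes moved both ways in p21 cells, 3 higher and 4 lower of 15 (adjusted p = 0.715): Dlk1 fell, as did H19, from 354.6 ± 271 to 102.6 ± 60.7 CPM (adjusted p = 0.0432), while Igf2 stood at 309.8 ± 139 against 337.2 ± 153 CPM (adjusted p = 0.828).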
